A study of Anthurium andraeanum with 18 samples.

How the data were processed

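The authors deposited 1 table of 132108 transcript groups assembled without a genome, with 2 values per library. The deposited counts are estimated read counts (expected counts), not normalised and not always whole numbers: 4.21% of the values have decimals. The other value per library, as deposited by the authors, reads as an abundance scaled to transcript length and library size (TPM), judged from its sum per library. How it was calculated is not given, and no comparison here uses it. The Length column is, per the file headers, the length of each transcript group in bases, with a median of 316 and a range of 201 to 16127. Identifiers begin with TRINITY, the naming of the Trinity assembler. Reads were trimmed with cutadapt 1.9 according to the submitters' processing notes. The assembler's version, the quantification tool and its filters are not given in the sources used here. Leaf RNA was extracted with Trizol and sequenced on an Illumina instrument.

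Here each transcript group is called a gene. A protein name was available in the table for 34998 genes. For 34370 genes the best hit was counted as a plant hit, which means any named genus other than Escherichia, without a check of taxonomy. Names and symbols are those in the table, and they come from similarity to proteins of other species. No name was inferred from an identifier. Several groups of 1 gene, or of close relatives, can share reads, so a change can in part reflect how reads were divided among them.

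The estimated counts were rounded and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 51670 genes, 25079 of them with a protein name. Counts were scaled by TMM, and 1 quasi-likelihood model with 6 group means was fitted to all 18 libraries. The p-values were adjusted by Benjamini and Hochberg's method within each comparison. A gene was called when its adjusted p was below 0.05 and its absolute log2 fold change was at least 1. Fold changes are printed with an approximate standard error (SE): the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic. Levels in counts scaled to library size (CPM) are printed as the mean and SD of 3 libraries. Principal components used log2 CPM with a prior count of 2.

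In total 37 gene lists were defined from words in the protein names, in the themes cold regulators, protection, photosynthesis, pigments, sugars, lipids, hormones, signalling, transcription factors, growth and surface, cell types and organelles. Each list was tested against the other genes with camera (limma 3.58.1) at its preset correlation of 0.01, and again with a correlation estimated from the residuals. The lists, comparisons, thresholds and alternative settings were chosen before the data were examined. Members were called by the adjusted p over all 51670 genes, and a second count was adjusted over the list alone.

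Genes were named by a fixed rule. For each comparison these were the 5 largest rises and the 5 largest falls among called genes that reached 10 CPM in the higher group, 1 per protein name, with no overlap between groups in comparisons of 2 groups. For each list these were the member with the highest mean and the called member with the lowest adjusted p. The rule gave 717 results over 9 comparisons.

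The other settings tried were DESeq2 1.42.0 size factors, its Wald test, quantile normalisation, no filter, a filter of at least 50 counts in 3 libraries, genes with a plant protein hit alone, no fold minimum, only the groups compared, a block for the replicate number, and leaving out each library in turn. For genes, the quantile setting used limma's trend method on log2 CPM in place of edgeR, so it changed scaling and test together. Replicate numbers do not pair the libraries: within cultivars the 18 pairs that share a number had residual correlations of -0.066 to 0.104. The model was tested on simulated data with the design of Oregon at 4 °C against 25 °C and 200 changed genes. It recovered 6% of 2-fold, 26.9% of 4-fold and 56.1% of 16-fold changes, with 5 false calls (7.8% of the calls). Recovery was counted by adjusted p alone, without the fold minimum. The simulated genes kept the spread of the real ones and their mean over all libraries, without differences between groups. Only 200 of 51670 genes changed there, while 25317 were called in the real comparison, so these percentages do not describe recovery in the real data.

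Where a group had 0 counts, a fold is a lower bound against 3 counts over the whole group. With 1 to 3 counts, the ratio is given with its 95% counting interval. Such bounds and intervals cover counting error only. The labels call the 3 libraries of a group biological replicates, but nothing says whether each is a separate plant, so p-values measure the spread between these samples. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.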

Results

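RNA of leaves from full-flowering Anthurium andraeanum plants was sequenced in 2 cultivars, Oregon and Fantasy Love, at 3 temperatures. Control plants stayed at 25 °C. Their time label is 0 days while the titles of the Oregon controls say 3 days, so it is not known whether controls and cold leaves were of the same age or collected on the same day. The other plants spent 3 days at 15 °C, then 3 days at 6 °C and then 3 days at 4 °C, under 12 h of light per day. Leaves were sampled at 25 °C, after the days at 6 °C and after the days at 4 °C, so plants sampled at 4 °C had also spent longer in the cold. Each of the 6 groups had 3 libraries, and the labels do not give the time of day of collection. The libraries held 14769909 to 21911024 estimated counts. All group values below are means ± SD of n = 3 libraries in counts scaled to library size (CPM), and log2 fold changes are given ± SE. Identifiers are printed without their common prefix TRINITY_.

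The share of light-harvesting transcripts was lower in the cold groups of both cultivars. Light-harvesting proteins took 5.77 ± 0.695% of all counts in Oregon at 25 °C, 0.05 ± 0.009% at 6 °C and 0.079 ± 0.009% at 4 °C. In Fantasy Love the shares were 5.64 ± 0.521%, 0.216 ± 0.096% and 0.051 ± 0.008%. With every library thinned to 14769909 counts, 67282 ± 3006 genes were detected in Oregon at 25 °C, 90136 ± 277 at 6 °C and 91524 ± 3712 at 4 °C. Fantasy Love gave 67186 ± 2588, 73226 ± 13876 and 82889 ± 8292 genes at the same 3 temperatures, and its replicate 2 at 6 °C, with 58735 genes, lay below the lowest of its controls, with 64300. The 100 most abundant genes took 28.6 ± 0.688% of the counts in Oregon at 25 °C and 14.8 ± 0.244% at 6 °C.

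Temperature was the main axis of variation between libraries and cultivar the next. The first principal component held 50.7% of the variance and the second 17.7%. Replicate 2 of Fantasy Love at 6 °C lay between the cold and the control libraries of its cultivar and had 59649 genes detected, the fewest of the 18 libraries. Its share of counts in genes named like ribosomal RNA was 4.21%, against 0.19 to 1.06% in the other 17 libraries. With this library left out, 23915 genes in place of 20870 were called between 6 °C and 25 °C in Fantasy Love.

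**Figure D1:**
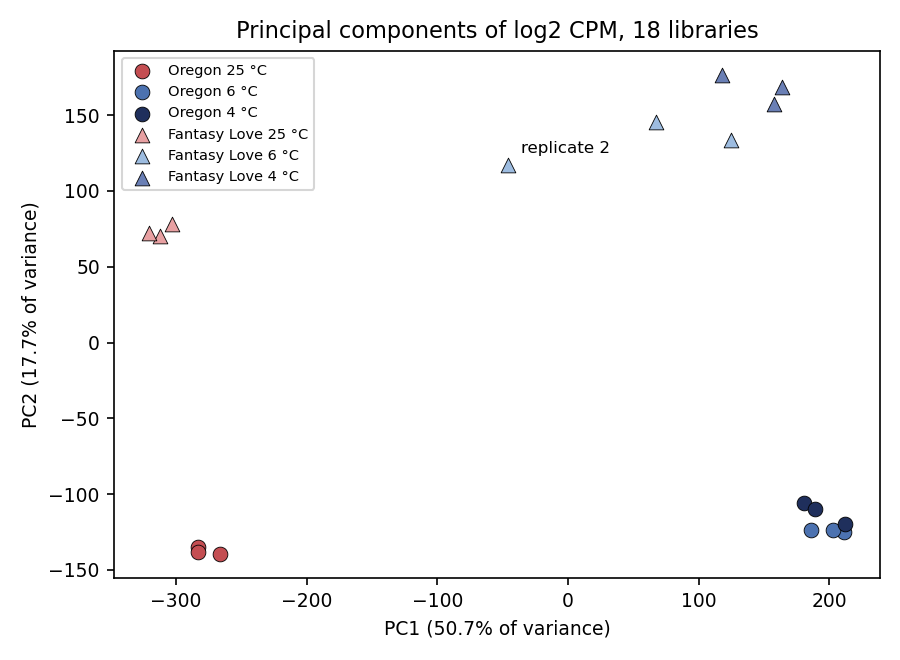
Each point is 1 of the 18 libraries, placed by its first (50.7% of variance) and second (17.7%) principal component of log2 CPM, with circles for Oregon, triangles for Fantasy Love and colours for temperature. The 25 °C libraries lie on the left, and replicate 2 of Fantasy Love at 6 °C lies between them and the other cold libraries.

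The first comparison asks which leaf genes changed in Oregon after the days at 6 °C. Transcripts of photosynthesis fell: the chlorophyll a-b binding protein of LHCII type I (DN35270_c0_g1), a main antenna protein, fell from 11400 ± 2020 to 11.7 ± 3.09 CPM, a log2 fold change of -9.92 ± 0.81 (adjusted p = 3.7e-08). CAB6A (DN36170_c0_g4), an antenna protein of photosystem I, fell from 7440 ± 928 to 45.2 ± 6.4 CPM. CHLH (DN49634_c0_g1), the magnesium chelatase subunit that opens the chlorophyll branch, fell from 1500 ± 127 to 42.4 ± 1.08 CPM. SGR (DN38584_c0_g5), the STAY-GREEN protein that starts chlorophyll breakdown, rose from 1.2 ± 1.12 to 997 ± 238 CPM. The most abundant catalase, CAT3 (DN47565_c0_g2), which removes hydrogen peroxide, fell from 5700 ± 431 to 235 ± 26.5 CPM.

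Of 51670 genes tested, 14602 rose and 10402 fell in Oregon at 6 °C. The median of all genes moved by 0.36 on the log2 scale with TMM, by 0.47 with DESeq2 size factors and by 0 with quantile normalisation. Fold changes near that size depend on the scaling, and some larger ones, such as that of RBCS below, moved further under quantile normalisation. Of 88 photosystem and light-harvesting genes, 60 fell and 3 rose (60 and 3 adjusted over the list alone; camera adjusted p = 9.12e-38). Of 32 chlorophyll synthesis genes, 22 fell and 1 rose, the same counts as when adjusted over the list alone (camera adjusted p = 9.88e-15). CHLP (DN33130_c0_g8), which makes the phytol tail of chlorophyll, fell from 1310 ± 277 to 131 ± 21.2 CPM. In the Calvin cycle list 14 of 35 genes fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 1.19e-06; adjusted p = 0.0904 with an estimated correlation). The aldolase ALDP (DN53300_c0_g1) of that cycle fell from 6320 ± 492 to 501 ± 68.5 CPM. The rubisco small subunit RBCS (DN57201_c1_g3) went from 11700 ± 902 to 5530 ± 280 CPM, with a log2 fold change of -1.08 ± 0.33 under TMM, -0.97 under DESeq2 size factors and 0.97 under quantile normalisation.

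Several genes tied to stress signalling rose in Oregon at 6 °C. The drought regulator DREB2B rose in 2 forms, from 1.04 ± 0.358 to 136 ± 25.1 CPM (DN53016_c0_g1) and from 7.76 ± 2.31 to 152 ± 13.8 CPM (DN40275_c0_g1). In the CBF, DREB and ICE1 list 5 of 10 genes rose and 5 fell (camera adjusted p = 0.567). ERF110 (DN33949_c0_g1), an ethylene-responsive factor, rose from 0.329 ± 0.0641 to 416 ± 60.9 CPM, and the ethylene-forming oxidase ACO1 (DN50246_c0_g1) rose from 9.25 ± 5.42 to 2090 ± 373 CPM. Of 65 jasmonate genes 40 rose and 12 fell, the same when adjusted over the list alone (camera adjusted p = 0.000103; adjusted p = 0.264 with an estimated correlation). OPR5 (DN53763_c0_g1), a reductase of the jasmonate pathway, rose from 2.8 ± 1.01 to 107 ± 12.5 CPM. WRKY factors rose in 31 of 59 cases and fell in 10 (32 and 10 adjusted over the list alone; camera adjusted p = 0.00051; adjusted p = 0.25 with an estimated correlation), led in level by WRKY24 (DN46003_c1_g3), from 18.2 ± 6.33 to 904 ± 163 CPM. NAC factors rose in 23 of 55 cases and fell in 3 (22 and 3 adjusted over the list alone; camera adjusted p = 0.000685; adjusted p = 0.168 with an estimated correlation), and NAC48 (DN52010_c1_g3) rose from 96.4 ± 9.69 to 2320 ± 362 CPM.

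Several genes tied to protection also rose in Oregon at 6 °C. HSP23.6 (DN46798_c1_g4), a small heat shock protein of mitochondria, rose from 9.15 ± 3.29 to 2580 ± 464 CPM, and 49 of 100 heat shock and chaperone genes rose while 7 fell, the same when adjusted over the list alone (camera adjusted p = 8.34e-05; adjusted p = 0.473 with an estimated correlation). The dehydrin COR410 (DN40128_c2_g5), which protects membranes when cells lose water, rose from 112 ± 25.5 to 713 ± 235 CPM. Galactinol synthase GOLS1 (DN52329_c1_g3) and the raffinose synthase RFS (DN48583_c0_g2), which make raffinose sugars, rose from 54.7 ± 3.94 to 1130 ± 350 CPM and from 0.538 ± 0.215 to 280 ± 170 CPM. Sugar and raffinose genes rose in 41 of 87 cases and fell in 16 (42 and 17 adjusted over the list alone; camera adjusted p = 0.0152; adjusted p = 0.596 with an estimated correlation). The chloroplast omega-3 desaturase FAD7 (DN33719_c0_g1), which makes trienoic fatty acids, rose from 63 ± 21.3 to 893 ± 189 CPM.

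Several genes of growth and the leaf surface fell in Oregon at 6 °C. XTH30 (DN54999_c0_g3), a wall-loosening enzyme, fell from 5500 ± 777 to 326 ± 55.5 CPM, and the cellulose synthase CESA1 (DN47563_c0_g3) fell from 436 ± 53 to 33.3 ± 10.3 CPM. Of 176 cell wall genes 95 fell and 25 rose (98 and 27 adjusted over the list alone; camera adjusted p = 1.37e-08; adjusted p = 0.169 with an estimated correlation). Of 101 cuticle and wax genes 58 fell and 10 rose (60 and 11 adjusted over the list alone; camera adjusted p = 2.79e-07; adjusted p = 0.168 with an estimated correlation). The gibberellin-regulated protein GASA1 (DN38282_c1_g2) fell from 1300 ± 573 to 3.81 ± 1.26 CPM. The clock protein LHY (DN52605_c1_g1), which peaks near dawn, fell from 152 ± 4.75 to 23.7 ± 1.13 CPM. Some genes with 0 counts at 25 °C were clearly expressed at 6 °C. GH3.1 (DN40974_c4_g4), which conjugates auxin, was at least 610-fold higher at 6 °C. The ubiquitin ligase PUB23 (DN47613_c2_g3) was at least 508-fold and the ethylene-pathway synthase ACS1 (DN41499_c0_g3) at least 365-fold higher. The receptor kinase LECRK82 (DN42225_c0_g5) was at least 417-fold lower.

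The second comparison asks how Oregon leaves stood at the end of the treatment, after the days at 4 °C, against the same controls. Light-harvesting genes were again far below the controls: LHCII type I (DN35270_c0_g1) was at 17.4 ± 6.73 CPM against 11400 ± 2020, a log2 fold change of -9.36 ± 0.79 (adjusted p = 6e-08), and LHCB4.1 (DN41704_c2_g2) fell from 5080 ± 722 to 68.3 ± 14.6 CPM. CAO (DN45615_c0_g4), which makes chlorophyll b, fell from 62.6 ± 13.4 to 2.81 ± 0.902 CPM. HSP23.6 (DN46798_c1_g4) rose to 4620 ± 466 CPM and COR410 (DN40128_c2_g5) to 1280 ± 270 CPM. The water channel TIP2-1 (DN32593_c0_g2) of the vacuole membrane fell from 139 ± 30.3 to 9.91 ± 2.04 CPM.

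In this comparison 14674 genes rose and 10643 fell, with a median of all genes at 0.39 under TMM, 0.48 under DESeq2 size factors and 0.05 under quantile normalisation. Photosystem genes fell in 53 of 88 cases and rose in 6 (54 and 6 adjusted over the list alone; camera adjusted p = 2.55e-25). Chlorophyll synthesis genes fell in 19 of 32 cases and rose in 0, as when adjusted over the list alone (camera adjusted p = 3.36e-10; adjusted p = 0.0759 with an estimated correlation). Calvin cycle genes fell in 11 of 35 cases and rose in 3 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0102, 0.446 under quantile normalisation; adjusted p = 0.262 with an estimated correlation). SGR (DN38584_c0_g5) rose to 359 ± 96.3 CPM, while CLH1 (DN46675_c1_g2), a chlorophyllase, fell from 81.2 ± 0.588 to 5.87 ± 1.31 CPM.

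Heat shock and chaperone genes rose in 58 of 100 cases in Oregon at 4 °C and fell in 7 (59 and 7 adjusted over the list alone; camera adjusted p = 5.83e-09; adjusted p = 0.207 with an estimated correlation). DREB2B (DN53016_c0_g1) reached 380 ± 161 CPM from 1.04 ± 0.358. The trehalose phosphatase TPPG (DN51509_c0_g1) rose from 10.4 ± 1.8 to 400 ± 106 CPM, and the glutathione transferase GSTU17 (DN56485_c2_g1) rose from 6.67 ± 0.456 to 134 ± 13.3 CPM. Ribosomal protein genes rose in 114 of 365 cases and fell in 31, as when adjusted over the list alone (camera adjusted p = 0.0389; adjusted p = 0.731 with an estimated correlation). RPL19A (DN56216_c0_g2), of the cytosolic ribosome, rose from 19.1 ± 4.15 to 589 ± 48.3 CPM. The ethylene-responsive factor CRF3 (DN46960_c1_g1) rose from 2.84 ± 0.751 to 286 ± 21 CPM, and the clock-related REVEILLE 1 (DN52212_c0_g1) rose from 2.78 ± 1.52 to 54 ± 6.95 CPM.

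Lists of the leaf surface, wall and water channels were also tested in Oregon at 4 °C. Of 101 cuticle and wax genes 63 fell and 6 rose (65 and 7 adjusted over the list alone; camera adjusted p = 1.87e-11; adjusted p = 0.078 with an estimated correlation). The lipase At4g10955 (DN52535_c0_g1) of that list fell from 39.5 ± 2.51 to 2.82 ± 0.0476 CPM. Cell wall genes fell in 93 of 176 cases and rose in 20 (95 and 22 adjusted over the list alone; camera adjusted p = 2.13e-09; adjusted p = 0.146 with an estimated correlation). Aquaporins fell in 24 of 37 cases and rose in 4 (25 and 4 adjusted over the list alone; camera adjusted p = 9.46e-06; adjusted p = 0.146 with an estimated correlation). Lignin genes fell in 30 of 61 cases and rose in 5 (31 and 5 adjusted over the list alone; camera adjusted p = 7.33e-05; adjusted p = 0.146 with an estimated correlation), among them the reductase SNL6 (DN48501_c1_g1), from 185 ± 4.76 to 23.1 ± 3.1 CPM. The cell death regulator LSD1 (DN34170_c1_g4) fell from 374 ± 62.5 to 9.15 ± 3.7 CPM. The alkaloid enzyme BBE1 (DN54073_c0_g11) was at least 997-fold lower than at 25 °C, and CYP86B1 (DN39692_c0_g7), a fatty acid hydroxylase of suberin, at least 849-fold. Lists of other kinds moved too: guard cell genes fell in 8 of 13 cases and rose in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0102; adjusted p = 0.146 with an estimated correlation), and cell cycle genes fell in 53 of 132 cases and rose in 21, as when adjusted over the list alone (camera adjusted p = 0.00324; adjusted p = 0.173 with an estimated correlation).

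**Figure D2:**
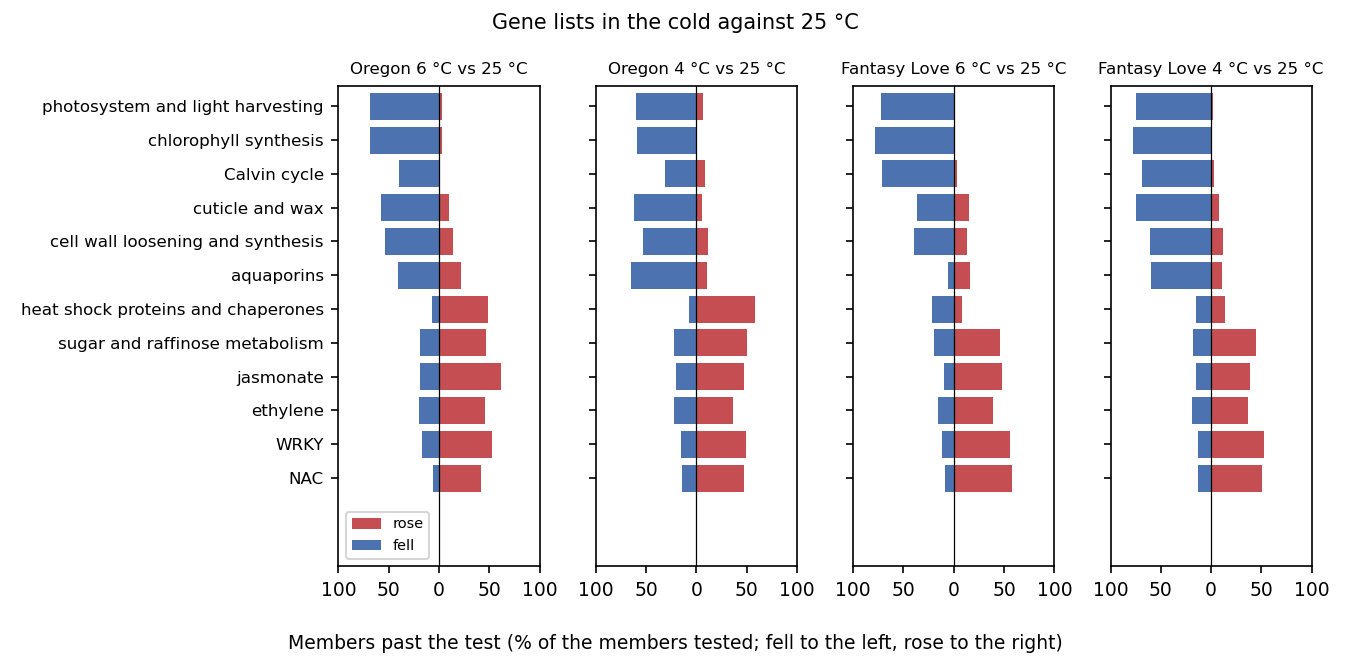
Bars show the percentage of tested members of 12 gene lists that rose (red, right) or fell (blue, left) in each of the 4 comparisons of cold with 25 °C leaves (edgeR, adjusted p below 0.05 and at least 2-fold). Photosystem genes fell in 60 of 88 cases in Oregon and 64 of 88 in Fantasy Love at 6 °C, while heat shock genes rose in 49 of 100 cases in Oregon and 8 of 100 in Fantasy Love.

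The third comparison asks the same of Fantasy Love after the days at 6 °C. LHCII type I (DN35270_c0_g1) fell from 7830 ± 999 to 174 ± 152 CPM, a log2 fold change of -5.49 ± 0.66 (adjusted p = 4.4e-06), or -6.4 without replicate 2 at 6 °C, and LHCB4.1 (DN41704_c2_g2) fell from 7290 ± 592 to 160 ± 61.3 CPM. ALDP (DN53300_c0_g1) fell from 14300 ± 651 to 1180 ± 205 CPM, with a log2 fold change of -3.61 ± 0.24, or -2.11 under quantile normalisation. WRKY24 (DN46003_c1_g3) rose from 4.29 ± 2.24 to 433 ± 63.2 CPM, and LEA5 (DN52422_c2_g1), a late embryogenesis protein tied to drying, rose from 19.6 ± 15.1 to 751 ± 290 CPM. PER21 (DN36590_c2_g3), a secreted peroxidase, fell from 1100 ± 441 to 7.08 ± 3.51 CPM.

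Here 12279 genes rose and 8591 fell, 58.8% of the calls being rises, against 9793 and 10312 (48.7% rises) under quantile normalisation. The median of all genes lay at 0.30 under TMM, 0.32 under DESeq2 size factors and 0.04 under quantile normalisation. With a model of these 2 groups alone 11738 genes were called. Photosystem genes fell in 64 of 88 cases and rose in 1 (65 and 1 adjusted over the list alone; camera adjusted p = 3.32e-39). Calvin cycle genes fell in 25 of 35 cases and rose in 1, as when adjusted over the list alone (camera adjusted p = 8.84e-16). Chlorophyll synthesis genes fell in 25 of 32 cases and rose in 0, as when adjusted over the list alone (camera adjusted p = 1.43e-17), and HEME1 (DN50001_c1_g1), an early enzyme of that pathway, fell from 137 ± 12.6 to 14.6 ± 5.06 CPM. RBCS (DN57201_c1_g3) fell from 19000 ± 179 to 6760 ± 3630 CPM, a log2 fold change of -1.49 ± 0.33 that was not past the test with the 2 groups alone (-1.39) or under quantile normalisation (-0.55). CHLH (DN49634_c0_g1) fell from 2120 ± 192 to 213 ± 196 CPM and SGR (DN38584_c0_g5) rose from 3.52 ± 1.83 to 158 ± 189 CPM. Single libraries moved both: the log2 fold change of CHLH was -3.31 with all libraries and -4.43 without replicate 2 at 6 °C, and that of SGR was 5.49 with all and 3.78 without replicate 3. Genes encoded in the chloroplast fell in 26 of 69 cases and rose in 6, as when adjusted over the list alone (camera adjusted p = 0.00122, or 0.332 with an estimated correlation), and without replicate 2 at 6 °C 23 of 75 fell and 11 rose.

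Several signalling genes rose in Fantasy Love at 6 °C. NAC factors rose in 32 of 55 cases and fell in 5 (32 and 6 adjusted over the list alone; camera adjusted p = 7.24e-07; with an estimated correlation 0.0266, and 0.0818 without replicate 2 of the 6 °C group). WRKY factors rose in 33 of 59 cases and fell in 7, as when adjusted over the list alone (camera adjusted p = 7.24e-07; with an estimated correlation 0.0496, and 0.135 without the same library). Calcium signalling genes rose in 113 of 242 cases and fell in 31, as when adjusted over the list alone (camera adjusted p = 4.42e-05; adjusted p = 0.084 with an estimated correlation). The calcium-binding protein CML45 (DN42729_c1_g2) rose from 0.371 ± 0.145 to 86.8 ± 27.7 CPM. DREB2B (DN40275_c0_g1) rose from 1.1 ± 0.129 to 100 ± 13.4 CPM, and CRF3 (DN46960_c1_g1) rose from 1.22 ± 0.473 to 90.5 ± 55.9 CPM. The jasmonate repressor TIFY 10a (DN40934_c0_g1) rose from 4.07 ± 1.26 to 218 ± 120 CPM, in a list where 31 of 65 genes rose and 6 fell (31 and 7 adjusted over the list alone; camera adjusted p = 7.22e-05; adjusted p = 0.29 with an estimated correlation). A TIFY 9-like gene (DN48782_c0_g2) was at least 750-fold higher than at 25 °C.

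LEA, dehydrin and cold-regulated genes rose in 7 of 14 cases and fell in 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.00974; adjusted p = 0.0815 with an estimated correlation). A galactinol synthase also named GOLS1 (DN50002_c0_g2), a different transcript group from that given for Oregon, rose from 2.2 ± 0.23 to 287 ± 246 CPM. Heat shock genes rose in 8 of 100 cases and fell in 22, as when adjusted over the list alone (camera adjusted p = 0.0098, 0.089 under quantile normalisation; adjusted p = 0.531 with an estimated correlation). Without replicate 3 at 25 °C, 8 of 104 rose and 22 fell, and the camera adjusted p was 0.0775. The chloroplast chaperone HSP90-5 (DN42041_c2_g1) fell from 261 ± 52 to 78.5 ± 11.8 CPM, and the ascorbate peroxidase APX8 (DN38778_c3_g1) of chloroplasts fell from 98.8 ± 9.02 to 11.7 ± 1.24 CPM. Cell wall genes fell in 69 of 176 cases and rose in 24 (70 and 24 adjusted over the list alone; camera adjusted p = 2.74e-05; adjusted p = 0.29 with an estimated correlation). LACS1 (DN55585_c1_g2), which activates fatty acids for wax, fell from 142 ± 15.5 to 12.6 ± 3.92 CPM. XTH30 (DN54999_c0_g3) fell from 945 ± 232 to 247 ± 288 CPM, a log2 fold change of -1.93 ± 0.54 that was -3.57 without replicate 2 of the 6 °C group and -1.84, not past the test, with the 2 groups alone. CAT3 (DN47565_c0_g2) had a log2 fold change of -1.5 ± 0.7 (adjusted p = 0.089) with all libraries and of -4.06, past the test, without that replicate.

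The fourth comparison asks how Fantasy Love stood after the days at 4 °C. LHCII type I (DN35270_c0_g1) fell to 11.7 ± 6.05 CPM, a log2 fold change of -9.38 ± 0.79 (adjusted p = 4.3e-08), and LHCB4.1 (DN41704_c2_g2) fell to 40.9 ± 2.56 CPM. PER21 (DN36590_c2_g3) fell from 1100 ± 441 to 0.322 ± 0.134 CPM. LAX3 (DN42557_c0_g2), an auxin importer, fell from 242 ± 96.4 to 0.351 ± 0.112 CPM. FDH (DN51344_c0_g4), a fatty acid elongase of the epidermis, fell from 297 ± 113 to 2.45 ± 1.76 CPM. COR410 (DN40128_c2_g5) rose from 85 ± 17.2 to 2090 ± 377 CPM.

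In Fantasy Love at 4 °C 14708 genes rose and 11150 fell, with a median of all genes at 0.39 under TMM, 0.40 under DESeq2 size factors and 0.15 under quantile normalisation. Photosystem genes fell in 66 of 88 cases and rose in 2, as when adjusted over the list alone (camera adjusted p = 1.1e-43). Calvin cycle genes fell in 24 of 35 cases and rose in 1 (camera adjusted p = 6.3e-14), and chlorophyll synthesis genes fell in 25 of 32 and rose in 0 (camera adjusted p = 1.8e-17), with the same counts adjusted over the list alone. CHLH (DN49634_c0_g1) fell to 35.9 ± 7.98 CPM from 2120 ± 192. RBCS (DN57201_c1_g3) fell from 19000 ± 179 to 4200 ± 709 CPM, a log2 fold change of -2.18 ± 0.34, against -0.11 and not past the test under quantile normalisation. CAT3 (DN47565_c0_g2) fell from 2120 ± 526 to 55.6 ± 28.5 CPM.

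Cuticle and wax genes fell in 75 of 101 cases and rose in 8 (75 and 9 adjusted over the list alone; camera adjusted p = 2.67e-15). Cell wall genes fell in 107 of 176 cases and rose in 20 (111 and 21 adjusted over the list alone; camera adjusted p = 2.2e-12; adjusted p = 0.0799 with an estimated correlation). The laccase LAC14 (DN42822_c2_g3), of the lignin list, fell from 480 ± 286 to 0.681 ± 0.613 CPM, and 33 of 61 lignin genes fell while 7 rose, as when adjusted over the list alone (camera adjusted p = 2.68e-05; adjusted p = 0.121 with an estimated correlation). Flavonoid and anthocyanin genes fell in 42 of 82 cases and rose in 10, as when adjusted over the list alone (camera adjusted p = 0.000404; adjusted p = 0.163 with an estimated correlation). CYP75A6 (DN52475_c1_g1), the flavonoid 3',5'-hydroxylase of blue pigments, fell from 305 ± 92.9 to 20.4 ± 5.48 CPM. Aquaporins fell in 22 of 37 cases and rose in 4, as when adjusted over the list alone (camera adjusted p = 0.000235; adjusted p = 0.205 with an estimated correlation), and TIP4-4 (DN47504_c0_g4) fell from 134 ± 46.6 to 6.62 ± 1.6 CPM. The proline-rich cell wall protein TPRP-F1 (DN37501_c3_g1) fell from 355 ± 224 to 0.0691 ± 0.0822 CPM. Lists of cell types and organelles fell as well, with the same counts adjusted over the list alone unless given: guard cells in 7 of 13 cases with 1 rise (8 and 1 over the list alone; camera adjusted p = 0.0251; adjusted p = 0.205 with an estimated correlation), floral MADS-box genes in 12 of 21 with 5 rises (0.0251, 0.106 under quantile normalisation; 0.161 with an estimated correlation), cell cycle genes in 49 of 132 with 20 rises (0.0114, 0.0816 under quantile normalisation; 0.205 with an estimated correlation) and chloroplast-encoded genes in 29 of 69 with 8 rises (0.00148; 0.25 with an estimated correlation).

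WRKY factors rose in 31 of 59 cases and fell in 8 (32 and 8 adjusted over the list alone; camera adjusted p = 0.000404; adjusted p = 0.161 with an estimated correlation). NAC factors rose in 28 of 55 cases and fell in 7 (30 and 7 adjusted over the list alone; camera adjusted p = 0.00202; adjusted p = 0.15 with an estimated correlation), with NAC48 (DN52010_c1_g3) going from 105 ± 9.19 to 1330 ± 187 CPM. DREB2B (DN40275_c0_g1) rose to 146 ± 29.7 CPM and ACO1 (DN50246_c0_g1) to 871 ± 361 CPM. JAR1 (DN55935_c1_g1), which makes the active form of jasmonate, fell from 401 ± 62 to 35.9 ± 6.85 CPM. Heat shock genes rose in 14 of 100 cases and fell in 15 (camera adjusted p = 0.654), and without replicate 3 of the 25 °C group 29 rose and 13 fell. HSP16.0 (DN35459_c0_g3), of peroxisomes, fell from 211 ± 53.2 to 44.5 ± 6.4 CPM, while HSP23.6 (DN46798_c1_g4) rose from 351 ± 229 to 1440 ± 244 CPM, a log2 fold change of 2.03 ± 0.46 (3.14 under quantile normalisation).

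**Figure D3:**
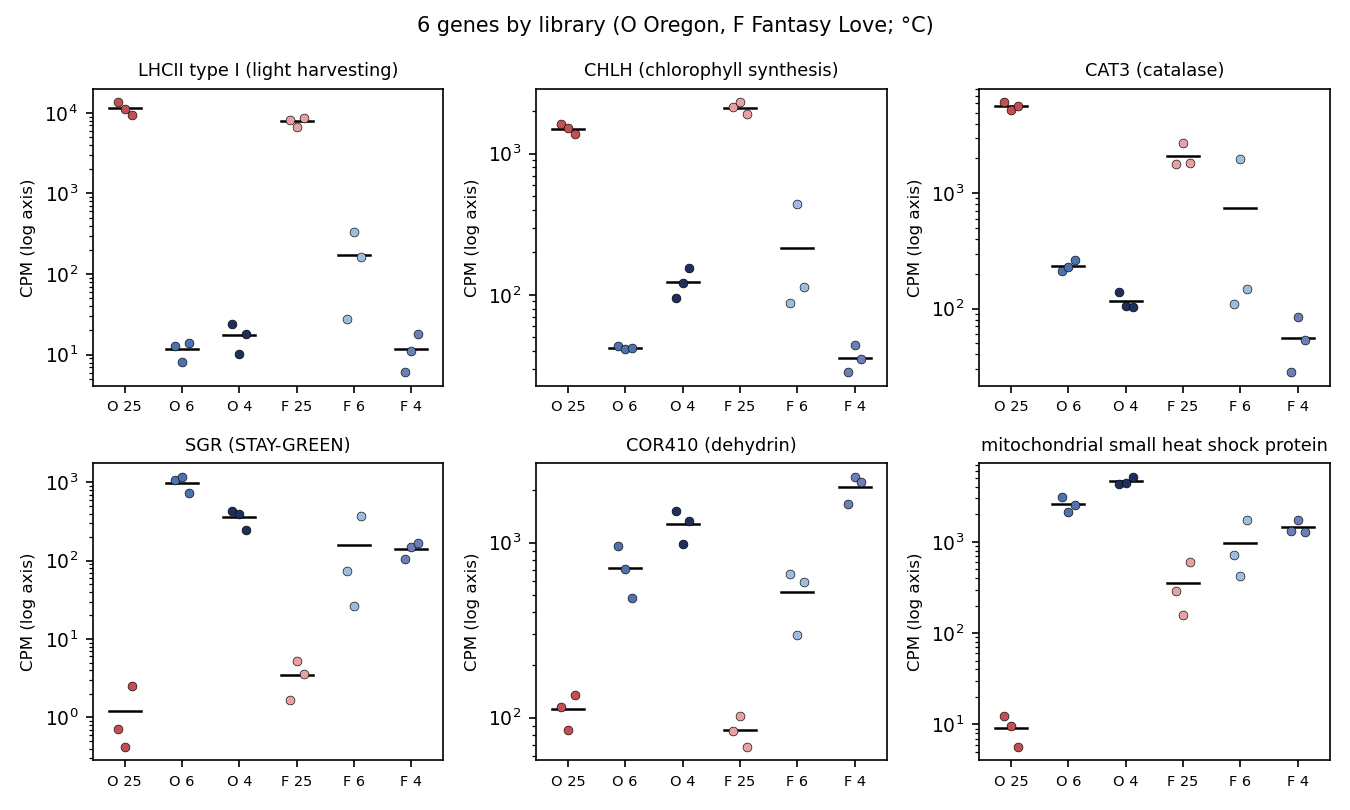
Each point is the CPM of 1 gene in 1 library on a log axis, with a line at the mean of the 3 libraries, for 6 genes in the 6 groups (O, Oregon; F, Fantasy Love; numbers, °C). LHCII type I fell from 11400 to 11.7 CPM in Oregon at 6 °C, while SGR rose from 1.2 to 997 CPM and COR410 reached 2090 CPM in Fantasy Love at 4 °C.

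The cultivars' cold responses can be set side by side, since they have separate controls. Both sets of calls come from 1 fit with a shared spread per gene, so part of any excess over independent calls can be built in. At 6 °C 8236 genes rose in both, where independent calls would share 3470, and 5882 fell in both, where 1730 would be shared. At 4 °C 9707 rose in both (4177 if independent) and 7427 fell in both (2297 if independent). Opposite calls were made for 327 genes at 6 °C and 287 at 4 °C. Log2 fold changes correlated between the cultivars with r = 0.685 at 6 °C and r = 0.733 at 4 °C over the 51670 genes. Calmodulin CCM1 (DN57124_c2_g1) rose in all 4 comparisons, by 1.51 ± 0.18 and 1.92 ± 0.18 on the log2 scale in Oregon and by 1.37 ± 0.18 and 1.36 ± 0.18 in Fantasy Love. SRK2E (DN40722_c1_g5), a kinase of abscisic acid signalling in guard cells, fell in all 4, from 27.8 ± 0.725 to 4.52 ± 0.74 and 3.81 ± 0.482 CPM in Oregon and from 46.9 ± 4.76 to 6.78 ± 1.01 and 4.16 ± 0.652 CPM in Fantasy Love.

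Going from 6 °C to 4 °C asks what the last step of cooling, with its 3 more days, changed in Oregon. Single genes of jasmonate and abscisic acid synthesis fell, and a photosystem gene rose. NAC029 (DN53939_c0_g2), a factor tied to leaf ageing, fell from 91.1 ± 21 to 9.67 ± 1.97 CPM, a log2 fold change of -3.24 ± 0.23 (adjusted p = 8.3e-07). LOX3.1 (DN53852_c0_g1), a lipoxygenase that starts jasmonate synthesis, fell from 208 ± 87.3 to 31.1 ± 8.75 CPM. NCED (DN38179_c0_g1), the enzyme that commits carotenoids to abscisic acid, fell from 42.6 ± 24.3 to 1.11 ± 0.214 CPM. PSBP (DN35016_c0_g4), of the oxygen-evolving complex, rose from 9.38 ± 1.69 to 27.2 ± 3.43 CPM.

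In this step 470 genes rose and 682 fell in Oregon. All its libraries at 4 °C and none at 6 °C held 2 CPM or more in human mitochondrial names. Differences in preparing or sequencing the libraries therefore cannot be told apart from the step. The count of 1152 was lower without any 1 of the 6 libraries. It was 347, 247 and 747 without replicates 1, 2 and 3 at 6 °C, and 819, 540 and 182 without replicates 1, 2 and 3 at 4 °C. These fits had 1 library fewer, and the filter kept 59136 to 60542 genes in place of 51670. The lower counts therefore do not show that the calls rest on particular libraries. It was 3734 with the 2 groups alone, 2205 under quantile normalisation and 2214 with the DESeq2 test. Jasmonate genes fell in 11 of 65 cases and rose in 0 (21 and 0 adjusted over the list alone, with camera adjusted p = 8.89e-13). AOS2 (DN34149_c0_g1), allene oxide synthase, was lower by a ratio of 743 (95% counting interval 205 to 6140). It stood at 24.1 ± 31.1 CPM at 6 °C, a spread between libraries that the counting interval does not cover. Aquaporins fell in 10 of 37 cases and rose in 0 (19 and 0 adjusted over the list alone; camera adjusted p = 1.93e-17), with TIP2-1 (DN32593_c0_g2) going from 63 ± 15.4 to 9.91 ± 2.04 CPM. Gibberellin genes fell in 4 of 35 cases and rose in 0 (9 and 0 adjusted over the list alone; camera adjusted p = 8.03e-07), and the growth repressor D8 (DN41075_c0_g3), a DELLA protein, fell from 38.1 ± 5.64 to 11.2 ± 0.801 CPM. EBF1 (DN54700_c2_g2), which limits ethylene signalling, fell from 139 ± 20.2 to 34.6 ± 4.68 CPM, IAA7 (DN45996_c0_g1), an auxin repressor, from 91.1 ± 16.5 to 21.4 ± 7.63 CPM, and WRKY6 (DN39331_c0_g2) from 85.8 ± 43.3 to 5.82 ± 1.4 CPM.

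Photosystem genes rose in 11 of 88 cases and fell in 0 from 6 °C to 4 °C in Oregon (15 and 0 adjusted over the list alone; camera adjusted p = 8.89e-13). Calvin cycle genes rose in 2 of 35 cases and fell in 0 (3 and 0 adjusted over the list alone; camera adjusted p = 1.66e-09). CHLI (DN32511_c0_g1), a magnesium chelatase subunit, rose from 25 ± 3.43 to 59.8 ± 8.28 CPM. Oxygen-scavenging genes rose in 9 of 89 cases and fell in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 7.29e-08), with APX8 (DN38778_c3_g1) going from 7.64 ± 0.845 to 18.6 ± 1.4 CPM. Ribosomal protein genes rose in 37 of 365 cases and fell in 0 (58 and 0 adjusted over the list alone; camera adjusted p = 1.48e-10; adjusted p = 0.253 with an estimated correlation), and RPL15 (DN36174_c0_g1) of the chloroplast ribosome rose from 62.9 ± 4.16 to 151 ± 10.7 CPM. HSP17.5-E (DN45800_c0_g1), a small heat shock protein, rose from 9.37 ± 1.3 to 42 ± 6.73 CPM. The 5 largest rises of this step among called genes that met the naming rule (10 CPM, no overlap of the groups) carried names of human mitochondrial genes, among them MT-CO1 (DN47895_c0_g5), at least 491-fold higher, and MT-CO3 (DN37038_c0_g9), higher by a ratio of 1440 (95% counting interval 258 to 57000). None of these 5 calls was past the test without replicate 1 or 2 at 6 °C or without replicate 3 at 4 °C. Genes encoded in the chloroplast rose in 5 of 69 cases and fell in 0 (9 and 0 adjusted over the list alone; camera adjusted p = 1.13e-05; adjusted p = 0.119 with an estimated correlation). The mitochondrial list, which holds animal genes, rose in 12 of 108 cases and fell in 0 (23 and 0 adjusted over the list alone; camera adjusted p = 0.00034; adjusted p = 0.0876 with an estimated correlation).

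The same step in Fantasy Love asks what changed there between 6 °C and 4 °C. Surface, wall and water genes fell: CER3 (DN52908_c1_g1), a wax alkane enzyme, fell from 107 ± 29.8 to 10.1 ± 1.1 CPM, a log2 fold change of -3.4 ± 0.3 (adjusted p = 3.6e-06). The lipase APG (DN45859_c2_g4) fell from 582 ± 281 to 0.215 ± 0.194 CPM and LAC14 (DN42822_c2_g3) from 378 ± 323 to 0.681 ± 0.613 CPM. LAX3 (DN42557_c0_g2) fell from 24.2 ± 12.3 to 0.351 ± 0.112 CPM, and the flowering repressor SVP (DN34549_c3_g1) fell from 10.4 ± 0.522 to 0.172 ± 0.221 CPM. Another transcript group named GOLS1 (DN44247_c0_g4), not one of those given above, rose from 19.3 ± 8.36 to 154 ± 49.9 CPM.

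Here 946 genes rose and 3715 fell, 20.3% of the calls being rises, against 2659 and 3349 (44.3% rises) under quantile normalisation. The count of 4661 became 7147 and 7312 without replicates 1 and 3 at 6 °C, 2765 without replicate 2 at 4 °C, and 463 with the 2 groups alone. Cuticle and wax genes fell in 56 of 101 cases and rose in 0 (60 and 1 adjusted over the list alone; camera adjusted p = 5.64e-30). Aquaporins fell in 22 of 37 cases and rose in 1 (25 and 3 adjusted over the list alone; camera adjusted p = 4.44e-16), and TIP4-4 (DN47504_c0_g4) fell from 66.9 ± 25.1 to 6.62 ± 1.6 CPM. Cell wall genes fell in 64 of 176 cases and rose in 0 (81 and 0 adjusted over the list alone; camera adjusted p = 2.24e-15; with an estimated correlation 0.0328, and 0.066 without replicate 2 at 6 °C). Flavonoid and anthocyanin genes fell in 27 of 82 cases and rose in 0 (36 and 0 adjusted over the list alone; camera adjusted p = 4.95e-10). RT (DN50538_c0_g2), which attaches sugar to anthocyanidins, fell from 25.3 ± 11.9 to 4.93 ± 1.12 CPM. Cell cycle genes fell in 21 of 132 cases and rose in 0 (27 and 0 adjusted over the list alone, with a camera adjusted p of 0.00152). With an estimated correlation their adjusted p was 0.0971, and 0.0361 without replicate 2 at 6 °C. Guard cell genes fell in 6 of 13 cases and rose in 0 (8 and 0 adjusted over the list alone, with camera adjusted p = 3.27e-05, or 0.0208 with an estimated correlation). Floral MADS-box genes fell in 7 of 21 cases and rose in 0 (9 and 1 adjusted over the list alone, with camera adjusted p = 6.84e-06, or 0.00963 with an estimated correlation).

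Photosystem genes fell further in Fantasy Love, in 39 of 88 cases with 0 rises (40 and 1 adjusted over the list alone; camera adjusted p = 1.65e-18). Replicate 2 at 6 °C had the highest light-harvesting share of its group, 0.3166% against 0.1245 and 0.2057%, and without it 33 of 89 genes fell and 1 rose (camera adjusted p = 5.33e-24). CAB6A (DN36170_c0_g4) fell from 162 ± 62.8 to 22.7 ± 5.23 CPM. PER42 (DN47090_c1_g2), a secreted peroxidase, fell from 46 ± 36 to 1.11 ± 0.706 CPM, and the lipoxygenase LOX2.3 (DN34003_c1_g1) fell from 103 ± 38.1 to 11.3 ± 0.605 CPM. The desaturase FAD12 (DN37542_c0_g1), which makes linoleic acid, fell from 269 ± 222 to 27.1 ± 4.13 CPM. Heat shock genes rose in 10 of 100 cases and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 6.81e-05; adjusted p = 0.335 with an estimated correlation), among them a mitochondrial 70 kDa protein (DN55199_c0_g2), from 6.52 ± 5.05 to 59.5 ± 10.7 CPM. COR410 (DN40128_c2_g5) rose from 520 ± 196 to 2090 ± 377 CPM, a log2 fold change of 2.01 ± 0.32 (1.96 and not past the test with the 2 groups alone). CAT3 (DN47565_c0_g2) fell by 3.76 ± 0.77 on the log2 scale, and by 1.26 without replicate 2 at 6 °C, and was not past the test with the 2 groups alone (-3.85). GASA1 (DN38282_c1_g2) had a log2 fold change of -3.57 ± 1.11 with that library and of 0.67, not past the test, without it.

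The cultivars were also compared with each other at 25 °C, to ask what separated them before any cold. Small heat shock proteins were among the genes higher in Fantasy Love: the 17.3 kDa class II protein (DN41420_c0_g1) was at 1770 ± 1880 CPM against 7.84 ± 3.08 in Oregon, a log2 fold change of 7.82 ± 0.68 (adjusted p = 4.6e-07; 6.44 without replicate 3 of Fantasy Love), and HSP23.6 (DN46798_c1_g4) was at 351 ± 229 against 9.15 ± 3.29 CPM (a log2 fold change of 5.26, or 4.6 without that replicate). PSBS (DN34330_c2_g1), which protects photosystem II from excess light, was at 7610 ± 358 against 1630 ± 265 CPM. The cytosolic ascorbate peroxidase APX1 (DN56298_c0_g1) was at 1500 ± 71.8 against 334 ± 55.9 CPM. Lower in Fantasy Love were LOX2.1 (DN55215_c3_g3), a jasmonate lipoxygenase, at 21.7 ± 8.04 against 620 ± 316 CPM, and CER1 (DN54048_c0_g2), a wax alkane enzyme, at 6.89 ± 1.52 against 108 ± 24.6 CPM.

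At 25 °C 4314 genes were higher and 3641 lower in Fantasy Love. Heat shock genes were higher in 43 of 100 cases and lower in 2 (48 and 4 adjusted over the list alone; camera adjusted p = 1.24e-13; adjusted p = 0.306 with an estimated correlation). Oxygen-scavenging genes were higher in 27 of 89 cases and lower in 4 (29 and 6 adjusted over the list alone; camera adjusted p = 1.49e-06; adjusted p = 0.216 with an estimated correlation). Calvin cycle genes were higher in 9 of 35 cases and lower in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 3.77e-06; adjusted p = 0.216 with an estimated correlation), with a phosphoglycerate kinase (DN55393_c0_g2) at 723 ± 100 against 145 ± 22.3 CPM. RFS (DN48583_c0_g2) was at 50.8 ± 23.6 against 0.538 ± 0.215 CPM. The sesquiterpene enzyme ZSS1 (DN41855_c0_g2) was at 374 ± 60 against 0.117 ± 0.148 CPM, and the resistance protein RGA1 (DN42613_c0_g2) at 272 ± 25.3 against 0.0897 ± 0.045 CPM. HMA2 (DN37961_c0_g9), a zinc transporter, was at least 951-fold lower in Fantasy Love, and the resistance protein RPS2 (DN38783_c4_g1) at least 520-fold, both with 0 counts there. Such values between cultivars hold for the assembled transcript group. Whether the other cultivar has another form of the gene in a separate group was not tested. WRKY24 (DN46003_c1_g3) was at 4.29 ± 2.24 against 18.2 ± 6.33 CPM, and XTH30 (DN54999_c0_g3) at 945 ± 232 against 5500 ± 777 CPM.

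**Figure D4:**
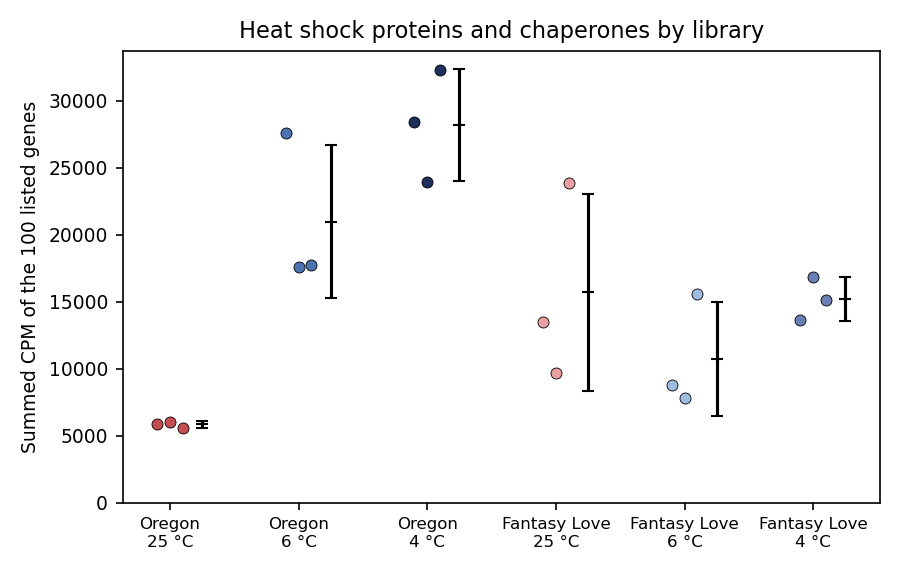
Points show the summed CPM of the 100 tested heat shock and chaperone genes in each of the 18 libraries, with bars for the mean ± SD of 3. Oregon rose from 5850 ± 249 at 25 °C to 28200 ± 4170 at 4 °C, while Fantasy Love stood at 15700 ± 7350 at 25 °C and 15200 ± 1640 at 4 °C.

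The last 2 comparisons ask whether the cultivars' cold responses differed, as an interaction of cultivar and temperature. A response here is the signed log2 fold change from 25 °C, and a lower one in Fantasy Love lies below that of Oregon. For genes that fell in both cultivars, a lower response is thus a deeper fall in Fantasy Love, and a higher one a smaller fall. Heat shock genes were among those that differed: HSP23.6 (DN46798_c1_g4) rose less in Fantasy Love by 6.69 ± 0.69 on the log2 scale at 6 °C (adjusted p = 2.9e-05) and by 6.95 ± 0.7 at 4 °C (adjusted p = 2e-05). Without replicate 3 of Fantasy Love at 25 °C these were 6.03 and 6.35, and the first was 7.48 without its replicate 3 at 6 °C. The 17.3 kDa class II protein (DN41420_c0_g1) differed by -7.93 ± 0.81 and -8.23 ± 0.81 (-6.54 and -6.92 without replicate 3 of Fantasy Love at 25 °C). At 6 °C 55 of 100 heat shock genes had a lower response in Fantasy Love and 1 a higher one (56 and 4 adjusted over the list alone; camera adjusted p = 4.16e-29; adjusted p = 0.118 with an estimated correlation). At 4 °C 45 were lower and 0 higher (58 and 1 adjusted over the list alone; camera adjusted p = 2.06e-28; adjusted p = 0.0539 with an estimated correlation). Without replicate 3 of Fantasy Love at 25 °C the counts were 46 and 0 at 6 °C and 41 and 0 at 4 °C, with estimated-correlation values of 0.0371 and 0.0239. The heat stress factor HSFA2B (DN35567_c1_g1) stood at 241 ± 162 CPM in Fantasy Love at 25 °C and 0.47 ± 0.164 at 4 °C, while Oregon went from 0.635 ± 0.336 to 5.33 ± 2.49 CPM.

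At 6 °C 2617 genes had a higher and 2052 a lower response in Fantasy Love. The count of 4669 was 2789, 3058, 2626 and 2796 without Oregon replicates 1 and 2 at 25 °C and 1 and 2 at 6 °C, 2944 without Fantasy Love replicate 3 at 25 °C, and 7288 without its replicate 3 at 6 °C. It was 3055 with the 4 groups alone and 7368 under quantile normalisation. Photosystem genes had a higher response in 21 of 88 cases and a lower one in 3 (26 and 5 adjusted over the list alone; camera adjusted p = 0.000128; adjusted p = 0.351 with an estimated correlation). Without replicate 2 of Fantasy Love at 6 °C, the library of its group with the highest light-harvesting share, these were 17 and 4 of 89 (camera adjusted p = 0.000275). CAB8 (DN55657_c0_g1), an antenna protein, fell from 9340 ± 1410 to 42.3 ± 6.07 CPM in Oregon and from 5800 ± 633 to 250 ± 96.3 CPM in Fantasy Love, a difference of 3.25 ± 0.39. LOX2.3 (DN34003_c1_g1) went from 266 ± 141 to 111 ± 25 CPM in Oregon and from 10 ± 3.29 to 103 ± 38.1 CPM in Fantasy Love. CML35 (DN50520_c0_g3), a calcium-binding protein, went from 96.5 ± 17.8 to 5.98 ± 2.89 CPM in Oregon and from 33.1 ± 13.1 to 70.5 ± 2.14 CPM in Fantasy Love. APX1 (DN56298_c0_g1) differed by -2.68 ± 0.26, EBF1 (DN54700_c2_g2) by -2.25 ± 0.36 and RFS (DN48583_c0_g2) by -6.07 ± 0.74 (-5.44 without replicate 1 of Oregon and -6.68 without replicate 3 of Fantasy Love at 6 °C). SGR (DN38584_c0_g5) differed by -4.21 ± 1.03, or by -5.28 without replicate 3 of Oregon at 25 °C and -5.92 without replicate 3 of Fantasy Love at 6 °C. Guard cell genes had a higher response in 3 of 13 cases and a lower one in 0 (4 and 0 adjusted over the list alone, with camera adjusted p = 0.00732, or 0.245 with an estimated correlation). Without replicate 3 of Fantasy Love at 25 °C none was called in either direction.

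At 4 °C 1993 genes had a higher and 2602 a lower response in Fantasy Love. The count of 4595 was 2891 without Oregon replicate 1 at 25 °C and 2971 without its replicate 3 at 4 °C, 7446 with the 4 groups alone and 8131 under quantile normalisation. Calvin cycle genes had a lower response, which for falling genes is a deeper fall, in 17 of 35 cases and a higher one in 0 (19 and 0 adjusted over the list alone; camera adjusted p = 4.06e-13). Photosystem genes, unlike at 6 °C, had a lower response in 21 of 88 cases and a higher one in 1 (25 and 1 adjusted over the list alone, with camera adjusted p = 1.67e-09, or 0.166 with an estimated correlation). Genes encoded in the chloroplast had a lower response in 6 of 69 cases and a higher one in 0 (7 and 0 adjusted over the list alone, with camera adjusted p = 0.0337, or 0.464 with an estimated correlation). RBCS (DN57201_c1_g3) differed by -1.83 ± 0.47, against -1.09 and not past the test under quantile normalisation. Oxygen-scavenging genes had a lower response in 24 of 89 cases and a higher one in 1 (26 and 3 adjusted over the list alone; camera adjusted p = 6.16e-07; adjusted p = 0.0979 with an estimated correlation), and PRXQ (DN44629_c0_g4), a chloroplast peroxiredoxin, went from 125 ± 30.4 to 132 ± 20.1 CPM in Oregon and from 549 ± 46 to 28.4 ± 3.64 CPM in Fantasy Love. GLUTRBP (DN52318_c0_g1), which steers the first step of chlorophyll synthesis, went from 47.2 ± 2.88 to 56.2 ± 4.79 CPM in Oregon and from 104 ± 10.7 to 17.5 ± 2.29 CPM in Fantasy Love. LAX3 (DN42557_c0_g2) differed by -5.68 ± 0.56 and CER3 (DN52908_c1_g1) by -3.64 ± 0.39. The 2 forms of DREB2B differed in opposite directions, DN40275_c0_g1 with a higher response in Fantasy Love by 3.10 ± 0.34 and DN53016_c0_g1 with a lower one by 2.4 ± 0.67 (adjusted p = 0.031). The second was not past the test in 8 of 12 fits with 1 library left out, with -1.58 without replicate 1 of Fantasy Love at 25 °C.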

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

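The interaction of cultivar and temperature was planned, and these tests were chosen after its result was seen: the other splits of the libraries and the 3 tests of the heat shock difference at 25 °C.

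The responses to cold differed between the cultivars by a test of the difference itself, for 4669 genes at 6 °C and 4595 genes at 4 °C. A lower response in Fantasy Love means a signed log2 fold change below that of Oregon, which for falling genes is a deeper fall. In the same test on gene lists, with all libraries, the Calvin cycle at 4 °C was the only list of that comparison past camera with an estimated correlation: 17 of 35 genes had a lower response in Fantasy Love and 0 a higher one (edgeR adjusted p over all genes; camera adjusted p = 4.06e-13; adjusted p = 0.0246 with an estimated correlation, and 0.0239 without replicate 3 of Fantasy Love at 25 °C, where heat shock genes passed as well). In 40 of 200 possible splits that exchange cultivars within a temperature, the real one included, 1 of 40 had a count as large, and the highest of the 39 others was 3776 at 6 °C and 1970 at 4 °C. Such splits mix the cultivars, so that differences between cultivars widen the spread within groups and lower the counts, and they do not decide whether chance can be excluded. The design names cultivar, so a genetic difference stays among the open explanations, as untested.

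Within these differences, heat shock genes were higher in Fantasy Love than in Oregon at 25 °C in 43 of 100 cases. The list was past camera (adjusted p = 1.24e-13) but not past camera with an estimated correlation (adjusted p = 0.306). This starting level enters both interactions. Replicate 3 of Fantasy Love at 25 °C had the highest summed level, 23896 CPM against 13510 and 9701 in replicates 1 and 2, but without it 34 of the 104 list members then tested were called higher. RNA of cold leaves in the control libraries is argued against as well: 188 genes that rose at least 64-fold in Oregon at 4 °C stood in Fantasy Love at 25 °C at a median of 1.12% of their level in Fantasy Love at 4 °C (quartiles 0.406 to 2.57%), where 40 heat shock genes, picked for being higher in Fantasy Love at 25 °C, stood at 78.2% (quartiles 49.2 to 166%). Handling or the time of collection of the control plants cannot be told apart from cultivar, since the labels give no handling and conflict on the time, and the names of the Fantasy Love controls carry the numbers 3, 5 and 6, so it is not known whether other control libraries were left out, and the summed heat shock levels of the 3 given differed by 2.46 times between the highest and the lowest. A difference between the cultivars may also explain the heat shock levels, and that stays untested.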

How the results depend on the processing

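The gene list results without Fantasy Love 6 °C replicate 2 or without Fantasy Love 25 °C replicate 3 were chosen after seeing the data, and the other alternatives were planned. The plans for other pseudocounts concern normalised values and were not run on counts.

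With stricter gene sets fewer genes were tested. Of the 25004 calls for Oregon at 6 °C, 16227 were still tested with at least 50 counts in 3 libraries, and 15948 were called again in the same direction. With plant protein hits only, 12121 were still tested and 11034 called again. The lower counts of that comparison thus came mostly from genes no longer tested. With at least 50 counts in 3 libraries the counts were 16259 and 16294 for Oregon at 6 and 4 °C against 25 °C and 16801 for Fantasy Love at 4 °C, but the counts were higher, at 1216 against 1152, for Oregon from 6 to 4 °C and, at 4644 against 4595, for the interaction at 4 °C. With plant protein hits only they were 11968, 12177, 10430 and 12800 for the 4 comparisons with 25 °C in the same order of cultivars and temperatures, and 4052 between cultivars.

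With only the groups compared, Fantasy Love at 6 °C against 25 °C gave 11738 genes. The step from 6 to 4 °C gave 3734 in Oregon and 463 in Fantasy Love. The interactions gave 3055 at 6 °C and 7446 at 4 °C. Between replicates, the chi-square per gene was 42.87 to 147.61 in Fantasy Love at 6 °C and 9.4 to 30.32 in the other groups. The main model gives each gene 1 spread for all 6 groups, so its p-values for Fantasy Love at 6 °C can understate the spread of that group. Quantile normalisation, tested with limma in place of edgeR, gave 2205 for the Oregon step and 7368 and 8131 for the interactions. The DESeq2 test gave 2214 for the Oregon step. The cause was not tested.

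Lists past camera numbered 17, 17, 17, 20, 23, 23, 5, 12 and 12 for the 9 comparisons in the order of the report. With an estimated correlation they were 2, 1, 5, 4, 8, 11, 0, 0 and 1, since that setting widens the error of lists whose members vary together. With the replicate block the comparison of cultivars had 8 lists in place of 5, and the cause was not tested.

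Leaving out 1 library gave 21935 to 23321 genes for Oregon at 6 °C, 22330 to 23807 for Oregon at 4 °C, 17897 to 23915 for Fantasy Love at 6 °C, 23745 to 25983 for Fantasy Love at 4 °C, 182 to 819 and 2765 to 7312 for the steps from 6 to 4 °C in Oregon and Fantasy Love, 5623 to 6618 between cultivars, and 2626 to 7288 and 2891 to 3764 for the interactions at 6 and 4 °C. The filter then kept 59038 to 61008 genes in place of 51670, so these fits changed the genes tested as well.

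Named genes were picked from the same data, in part for large folds or low adjusted p. That choice partly fixes their stability. Over all 1152 calls of the Oregon step, 181 were made again without replicate 3 at 4 °C and 1120 with DESeq2 size factors. Of 10964 values of named genes under alternatives, 10567 kept their direction and side of the threshold, 268 lost the call and 126 gained it. The sign turned in 3: under quantile normalisation RBCS (0.97 against -1.08) and the chloroplast reading frame ycf68 (1.38 against -0.16) in Oregon at 6 °C, and GASA1 in Fantasy Love from 6 to 4 °C, which ranged from -4.2 to 0.67 with 1 library left out and had the turned sign without 6 °C replicate 2 (-3.57 with all libraries). The cause was not tested.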

Other observations

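These tests were chosen after the result was seen: the mixture test of Fantasy Love 6 °C replicate 2 and the count of its genes without a name, the tests of animal transcripts, and the splits of libraries in the comparisons of 2 groups. The gene lists were planned, and the tests of that replicate for an Oregon label and for a non-plant organism were written down before their results were seen.

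Single genes of other processes changed in the cold. BAM1 (DN54800_c0_g1), a chloroplast beta-amylase, rose from 1.05 ± 0.541 to 74.2 ± 30.2 CPM in Oregon at 6 °C, while 11 of 39 starch breakdown genes rose and 7 fell (camera adjusted p = 0.881). The proline dehydrogenase POX1 (DN40438_c0_g1), which degrades proline, rose from 1.59 ± 0.648 to 56.8 ± 7.47 CPM there, in a list of 9 genes of which 1 rose and 1 fell (camera adjusted p = 0.865) and which also holds acetylornithine aminotransferases. Autophagy protein ATG8D (DN46491_c0_g2) rose from 6.6 ± 0.449 to 39.6 ± 3.27 CPM in Oregon at 6 °C and from 8.74 ± 0.799 to 67.6 ± 18.9 CPM in Fantasy Love at 4 °C. The protease ASPG1 (DN41031_c2_g4), known from guard cells, rose from 0.365 ± 0.194 to 20.4 ± 6.96 CPM in Oregon at 6 °C, while 7 of 13 guard cell genes fell and 2 rose (camera adjusted p = 0.0329; 0.264 with an estimated correlation). The auxin receptor TIR1 (DN41313_c0_g2) fell from 85.7 ± 6.17 to 3.02 ± 1.38 CPM, with 36 of 120 auxin genes falling and 30 rising (camera adjusted p = 0.252).

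The other lists in Oregon at 6 °C moved as follows. Of 14 LEA and dehydrin genes 5 rose and 1 fell (camera adjusted p = 0.303), of 242 calcium genes 82 rose and 45 fell (0.142, or 0.018 under quantile normalisation), and of 96 ethylene genes 44 rose and 19 fell (0.0492, or 0.503 with an estimated correlation and 0.0543 with the replicate block). Of 33 abscisic acid genes 9 rose and 10 fell, of 35 gibberellin genes 11 rose and 11 fell, and of 40 MAP kinase genes 15 rose and 7 fell. Of 89 oxygen-scavenging genes 17 rose and 21 fell (0.0718, or 0.0397 with the replicate block), of 22 class III peroxidases 9 rose and 7 fell, and of 20 chlorophyll breakdown genes 7 rose and 6 fell. Of 82 flavonoid genes 8 rose and 28 fell, of 61 lignin genes 9 rose and 25 fell (0.00365, or 0.264 with an estimated correlation), of 37 aquaporins 8 rose and 15 fell, and of 32 desaturation genes 10 rose and 8 fell. Of 65 senescence genes 11 rose and 18 fell, of 30 clock genes 5 rose and 12 fell (0.00746, or 0.0841 under quantile normalisation and 0.215 with an estimated correlation), and of 365 ribosomal genes 65 rose and 46 fell. Among lists of cell types and organelles, 1 of 6 phloem genes fell and 0 rose, 6 of 21 MADS-box genes rose and 8 fell, and 23 of 132 cell cycle genes rose and 44 fell (0.0152, or 0.114 under quantile normalisation and 0.264 with an estimated correlation). Of 69 chloroplast-encoded genes 7 rose and 22 fell (0.00128, or 0.344 with an estimated correlation), of 108 mitochondrial genes 29 rose and 16 fell, and of 1030 transposon genes 390 rose and 105 fell (0.00746, or 0.0541 under quantile normalisation and 0.483 with an estimated correlation). The lists are not pure: the flavonoid list holds ANTHOCYANINLESS 2, the MADS-box list holds ULTRAPETALA and AP2, and the mitochondrial list holds animal genes.

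Replicate 2 of Fantasy Love at 6 °C stood apart from the other 2 libraries of its group, with correlations of 0.867 and 0.857 with them, against 0.915 between those 2. A library made up only of other libraries of the series is argued against, since 163 genes at 10 CPM or more lay 4-fold above all other 17 libraries, where the highest count for another library was 26. A partial mixture of its own RNA with another library could keep such genes, so this count cannot decide on it. An Oregon library under its label is argued against too: 0% of 42 genes found only in Oregon reached 1 CPM in it, while 91.5% of 47 genes found only in Fantasy Love did. Of its 105 named genes 4-fold above all other libraries, 100% had a hit counted as a plant hit. The 95% Clopper-Pearson interval was 96.5 to 100, against 99.5% of all named genes. Since any genus but Escherichia counted, this cannot decide whether RNA of a non-plant organism was present. RNA of another plant, or a source of its 58 genes without a name, cannot be told apart without a genome either. No biological explanation was tested, since the design gives none for a single replicate.

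Some libraries held transcripts with animal names, of human mitochondria, mouse liver or haemoglobin, at most 0.373% of counts in replicate 3 of Oregon at 4 °C. Plant genes with animal-like names are argued against, since summed mouse-liver counts within Oregon at 25 °C differed by at least 687 times (2062 against 11 and 2, with the lowest library set to 3 counts). By counting error alone, a single source is argued against by the ratio of Mup11 to Alb in libraries with enough counts of both. It differed by 4.89 times, from 0.449 (95% interval 0.386 to 0.522) to 2.2 (1.97 to 2.45). Replicate 3 of Oregon at 4 °C, with 927 mouse-liver counts, was not among these libraries. Variation from preparing the libraries was not measured. Carryover at sequencing cannot be told apart from animal RNA in the tubes, as the labels give no lanes. In mouse-liver names 5 libraries were at 10 CPM or more, in human-mitochondrial names 8 at 2 CPM or more, and 1 at both. In human-mitochondrial names the Oregon libraries held 72, 64.1 and 317 CPM at 4 °C and 0.187, 0.466 and 0.362 CPM at 6 °C. Replicate 3 of Fantasy Love at 4 °C held 55.2 CPM, against 0.877 and 1.13 in replicates 1 and 2. Libraries at 25 °C were split within both cultivars. Preparation or sequencing that went with these names thus cannot be told apart from the Oregon step from 6 to 4 °C. No biological explanation was tested, and animal names made up 1.22% of the calls for Oregon from 6 to 4 °C, where the 5 largest rises that met the naming rule had human mitochondrial names, while the mouse gene Mup11 had the largest such rise in both interactions and Serpina1c the next at 4 °C.

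For each of the 7 comparisons of 2 groups, 10 splits of the 6 libraries are too few for a share under 0.05, and the real split was the 1 split with the largest count. The highest other split gave 0 genes against 25004 and 25317 for Oregon at 6 and 4 °C, 4 against 20870 and 0 against 25858 for Fantasy Love, 0 against 1152 for the step from 6 to 4 °C in Oregon, 706 against 4661 for that step in Fantasy Love, and 0 against 7955 between cultivars. These splits were fitted with edgeR. Each of the other splits mixes the 2 groups compared, so the difference between them widens the spread within groups and lowers the counts. The low counts of other splits therefore do not decide whether chance can be excluded.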
